A study of Homo sapiens with 220 samples.

How the data were processed

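Chromatin of LoVo cells was cross-linked with formaldehyde, sonicated and immunoprecipitated with antibodies raised in rabbits, goats or mice, and the libraries were sequenced as short single reads, per the labels' protocols. Reads were handled with CASAVA 1.4 and BWA, per the submitters' processing notes, and the coordinates are those of the human build hg18. Peaks were called for each library separately with MACS 1.4.0rc2 against the IgG library of the antibody's host, per the file headers. The headers give a p-value threshold of 1e-05, a band width of 300, model fold limits of 2 and 6, an effective genome size of 2.75e+09 and local background windows of 1000 and 10000 bp. These settings differed in 0 lists. Tag size was 30 to 36 bp and 36 bp in 112 lists, per the file headers. The IgG controls held 22736096 (rabbit), 37934038 (goat) and 30563935 (mouse) tags after filtering. The criteria behind the quality label are not given in the sources used here, and peak number could be among them. The title of the H3K4me3 sample says that it passed although its quality field gives no call, and it was used as a histone mark either way.

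Each list gives per peak the start, end and summit and 4 values. The tag count in the peak region is a raw count of that library, per the file headers. The score is the caller's p-value as -10 times its log10, as the authors deposited it, with no value under 50. The fold enrichment is the ratio of tags in the peak over the local background of the scaled control, per the file headers, and no deposited peak had a fold under 2. The false discovery rate is a percent that the caller estimated by exchanging sample and control, per the file headers. It was not used here, nor was an unnamed last column. Score and fold are the authors' values and were used only to rank peaks or describe them within 1 list. A peak list holds no signal outside its peaks, so a factor without a peak at a position is not shown to be absent there.

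Lists were read for chromosomes 1 to 22 and X, which left out 2924 of 2080227 peaks. Peak numbers of lists count all sequences, and shares of peaks use these chromosomes. Samples were grouped from their titles into passed factors (108), failed factors (99), cohesin (3), mediator (2) and 1 library each of NIPBL, CTCF, H3, H3K4me1 and H3K4me3. IgG samples entered no comparison, as the peak calls already use them. The labels also give the batch (69 passed and 39 failed libraries in batch 1, 39 and 60 in batch 2) and the host (60 passed and 23 failed rabbit, 19 and 45 goat, 29 and 31 mouse). Replicate numbers follow accession order and pair nothing.

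A region is a chain of passed-factor summits with gaps of at most 500 bp, and it is dense with at least 10 distinct factors. A peak is crowded when at least 10 other passed factors have a summit within 500 bp. A cohesin site joins summits of RAD21, SMC1A and SMC3 over gaps of at most 500 bp when at least 2 subunits take part, and its position is their mean. Distances from regions run from their first and last summit. Expected numbers came from 100 circular shifts of each list by a random offset on each chromosome. These shifts keep the spacing within a list but move peaks into unmappable or closed sequence as well, so they are a low bar. As an alternative, lists were shifted by 20 to 100 kb. The cohesin, NIPBL, mediator and histone libraries were made with rabbit antibodies and CTCF with a goat antibody, and the comparison of cohesin sites by the host of the factors was added after the results had been seen.

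Differences between groups of libraries were tested by two-sided permutation of labels with 100000 resamples, or by exact enumeration where a group had under 10 members and at most 1000000 splits existed. Paired differences over factors were tested by sign flips. Families with at least 3 passed members and lists of at least 500 peaks were compared with the remaining factors, as were the factors of no listed family taken as a group, and adjusted by the Benjamini-Hochberg method. For pairs of factors, log2((observed + 0.5)/(expected + 0.5)) was taken over 92821 regions with at least 2 factors. The expected number was the product of 1 weight per library, fitted within bins of the number of factors so that each library's expected pairs equalled its observed pairs. Family and host labels were permuted 10000 times over factors, and the mean of each partner list was compared with 10000 random lists of its size.

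The groups, tests, partner lists, 195 alternatives and the rule for naming factors were set before the data were examined. The rule took the CTCF, cohesin, mediator, NIPBL and histone libraries, the 5 highest and 5 lowest passed factors with at least 500 peaks in each measure, the members of partner lists, the 10 highest pairs, the 10 regions with the most factors and 5 with cohesin and no CTCF. Factors under 500 peaks and failed factors that are named were chosen after their values were seen, as was HINFP wherever it is singled out. Other choices came after the peak lists were opened: the chromosomes kept, the joining distance of cohesin sites, the bin edges, exact enumeration for small groups, and the use of score filters on factor lists with the marker lists kept whole. Batch, host and tag size subsets of passed and failed libraries kept crowding counted over all passed factors, whereas region counts and the crowded share of factor peaks used the subset throughout.

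The expected number of shared regions was first computed as the product of the lists' region numbers scaled within each bin. Results had been seen once when simulated lists showed that this method gave a difference between hosts for independent lists, and it was replaced by the fitted weights. The number of partner lists past the threshold changed from 2 to 1, and the host difference stayed at 0.23. The first method is kept among 42 alternatives added later.

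Computations were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9. The programs were tested on simulated data. For dense regions, real lists were shifted to be independent, and 199 of 200 planted clusters (99.5%) were found. For pair overlap, a planted pair ranked 1 among 5565. For pair overlap by host, 20 sets of independent lists gave differences of 0.0011 to 0.037, so a small positive offset is part of the method. Shifted lists of this kind have almost no dense regions, so the offset among crowded lists was not measured. Precision is limited by depth, since list length rose with tag number, and by the single library per factor. Positions were not matched to genes, because the annotation at hand was of another build and no coordinates were converted.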

Results

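Chromatin immunoprecipitation with sequencing was used to map transcription factor binding in LoVo, an established line from a human colon adenocarcinoma. The series held 220 samples, of which 217 had a peak list and 3 were IgG controls, 1 for each antibody host (rabbit, goat and mouse). By the submitters' quality label, 69 transcription factor libraries of batch 1 and 39 of batch 2 had passed, and 39 of batch 1 and 60 of batch 2 had failed. The other 10 lists were the cohesin subunits RAD21, SMC1A and SMC3, the cohesin loader NIPBL, the insulator protein CTCF, the mediator subunits MED1 and MED12, histone H3, and the histone marks H3K4me1 and H3K4me3. Each factor had 1 library, so the library was the unit of every comparison between groups, and the p-values measure the spread between libraries of different factors. After removal of duplicate tags, the median depth was 10805106 tags in passed libraries (lowest 1990040, highest 39047900) and 10932142 tags in failed libraries (lowest 1411935, highest 21217221). H3 was the deepest library with 62899799 tags, while H3K4me1 had 5540907 and H3K4me3 had 5713798.

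Libraries that had passed held more peaks than those that had failed, at nearly the same median depth. The median passed list had 8810 peaks (lowest 325 for MAZ, highest 45040 for JUND), and the median failed list had 2477 peaks (lowest 1, highest 22397). The largest passed lists belonged to JUND, a partner in the AP-1 complex, to HINFP, a zinc finger regulator of histone H4 genes (39728), to the homeodomain protein DLX1 (36723), to MYC (35623) and to ETS2 (33269). Among passed lists with at least 500 peaks, ZNF236 (733), NR2F2 (750), HES2 (1068), IRX3 (1563) and KLF3 (1599) had the fewest. Fewer than 500 peaks were called in 2 passed and 21 failed libraries. On the log10 scale the mean was 3.90 ± 0.418 (SD over the passed libraries) against 3.14 ± 0.907 (SD, n = 99 failed libraries), a difference of 0.759 (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The difference was 0.747 in batch 1 and 0.829 in batch 2, and it was 0.966 among goat, 0.413 among rabbit and 0.369 among mouse antibodies (highest of these permutation p-values 0.00543). With lists under 500 peaks left out it was 0.399 (permutation p = 1e-05).

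Deeper libraries gave longer lists. Across the passed libraries, log10 peak number and log10 tags after filtering had a Pearson r of 0.522 (permutation p = 1e-05, adjusted p = 1.8e-05 over 18 relations) and a Spearman rho of 0.427 (permutation p = 1e-05). The r was 0.507 without the 2 libraries farthest from the median depth, 0.418 within batch 1 and 0.620 within batch 2. Across the 99 failed libraries r was 0.748 and rho 0.607 (permutation p = 1e-05 for each, adjusted p of r = 1.8e-05), with r of 0.708 without the 2 farthest libraries, 0.703 within batch 1 and 0.769 within batch 2.

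The first question was whether factors bind in clusters, as the title of the series puts forward. Chaining the summits of the passed factors over gaps of at most 500 bp gave 250181 regions. In 157342 of them a single factor had a called summit, and 30100 were dense, with summits of at least 10 distinct factors. The dense regions were 12.03% of the regions, spanned 1.14% of the effective genome size and held 69.3% of all factor peaks. Their median length was 883 bp. The region with the most factors, 89, lay on chromosome 19 from 59664961 to 59667911 (hg18) and had cohesin, CTCF, NIPBL, MED1, MED12, H3K4me3 and H3 summits within 500 bp. Regions with 85 factors lay on chromosome 11 from 64400336 to 64403621, with CTCF, and on chromosome 21 from 37560620 to 37562393, without CTCF. Each of the 10 regions with the most factors had cohesin, NIPBL, both mediator subunits and H3K4me3. Summits of 10 to 23 of the 99 failed libraries also lay inside each of these regions. Whether calls in such crowded places reflect specific binding or general enrichment was not tested. Genes at these positions were not analysed here.

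Circular shifts of each list along its chromosomes gave 6.13 ± 2.47 dense regions (mean ± SD of 100 shifts, highest 12) in place of 30100 (one-sided p = 0.0099, the smallest that 100 shifts can give). Local shifts of 20 to 100 kb, which keep each list in its own part of the chromosome, gave far more, with a mean of 3258 and a highest of 3441 (one-sided p = 0.0099). Dense regions numbered 18069 with the 69 batch 1 libraries alone and 19310 with the 39 of batch 2. With 1 antibody host at a time they numbered 25891 for rabbit, 3899 for mouse and 1020 for goat. Without the regions that touched an H3K4me3 peak, 16948 remained, and 13504 were formed by 27 libraries, namely the longest list of each family and the 9 factors of no listed family.

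**Figure D1:**
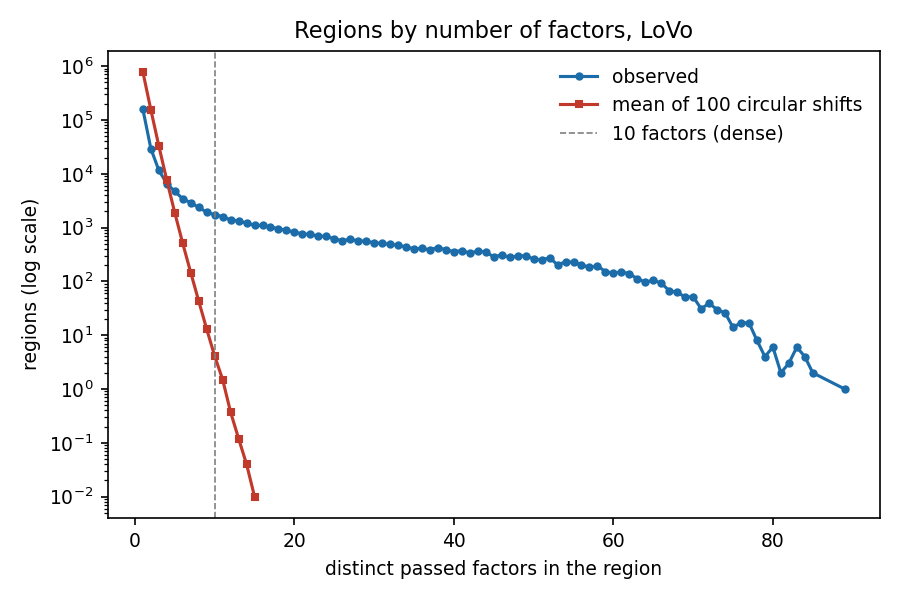
Number of regions (log scale) against the number of distinct passed factors in the region, observed (circles) and as the mean of 100 circular shifts of whole chromosomes (squares); the dashed line marks 10 factors. Observed regions reach 89 factors, whereas the circular shifts gave at most 12 regions with 10 or more factors; local shifts, not drawn, gave up to 3441.

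Most peaks of a typical factor lay in crowded places, with at least 10 other passed factors within 500 bp of the summit. The crowded share was 61.5% ± 14.7 (SD over the passed factors) and 0% in each of the 100 circular shifts (one-sided p = 0.0099, the smallest possible), with a mean of 0.0209% and a highest of 0.0338% in local shifts. It was highest for SP1, which binds GC boxes of promoters (95.5%), for CASP8AP2, a cofactor of histone gene expression (91.1%), and for GLI2 (86.6%), YY1 (86.3%) and GMEB2 (83.7%). It was lowest for HINFP (18.5%), TCF7L2, the main nuclear effector of Wnt signalling in the gut (19.5%), SMAD2 (33.2%), TCF12 (35.4%) and NFIL3 (37.9%). With 1 antibody host at a time, and the neighbours counted in that host alone, the share was 59.6% for rabbit (60 libraries), 17.6% for mouse (29) and 7.46% for goat (19). These subsets hold fewer possible neighbours, and with all passed factors as neighbours the shares were 64.995% for rabbit, 56.9% for mouse and 57.3% for goat. Over all passed factors it was 32.8% within 100 bp in place of 500 bp. It was 37.2% without the peaks that touched H3K4me3 and 39.2% with the 27 libraries of 1 list per family and the factors of no listed family.

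Failed libraries were crowded less often, at 26.6% ± 22.7 (n = 99) against 61.5% in passed ones, a difference of 34.9 percentage points (two-sided permutation test, p = 1e-05, the smallest possible). The difference was 32.99 in batch 1, 36.4 in batch 2, 21.9 for rabbit, 36.0 for mouse and 35.2 for goat antibodies, each with permutation p = 1e-05. It was 35.3 with log10 peak number as a covariate, and it fell to 19.4 within 100 bp as well as without the peaks that touched H3K4me3.

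The second question was where cohesin, the ring complex that holds sister chromatids and anchors chromatin loops, lies relative to these clusters. A cohesin site, called in at least 2 of the 3 subunit libraries, was found within 500 bp of 88.5% of dense regions (95% Wilson interval 88.1 to 88.9) and of 4.32% of single-factor regions (4.22 to 4.43). By subunit, SMC1A was at 91.2% of dense regions, SMC3 at 87.03% and RAD21 at 84.9%, a mean of 87.7% ± 3.19 against 4.62% ± 0.365 of single-factor regions (SD, n = 3 subunits). NIPBL, which loads cohesin onto chromatin, was at 84.2% of dense and 0.955% of single-factor regions. Of the mediator complex, which connects bound factors with RNA polymerase II, MED12 was at 87.1% of dense and 1.006% of single-factor regions, and MED1 at 53.6% and 0.184%. CTCF was at 28.2% of dense and 3.07% of single-factor regions. A single-factor region rests on the calls of 1 library, and the share of false calls among such regions was not estimated.

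The difference between dense and single-factor regions was 84.2 percentage points for cohesin sites, 83.2 for NIPBL and 69.8 for the mean of both mediator lists. Circular shifts gave a mean difference of 2.43 (highest 2.86) for cohesin, 1.52 (highest 2.76) for NIPBL and 1.15 (highest 1.32) for mediator (two-sided p = 0.0099 for each, the smallest that 100 shifts can give). Local shifts gave 5.53 (highest 5.96), 4.05 (highest 4.54) and 3.42 (highest 3.70), with the same p. Measured from the middle of each region, which removes the advantage of longer regions, the differences were 74.3 for cohesin, 73.96 for NIPBL and 61.9 for mediator. For regions built from batch 1 or batch 2 libraries alone the cohesin difference was 86.1 and 81.3. The Wilson intervals cover counting error only, and neighbouring regions are not independent.

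The shares of cohesin, NIPBL, both mediator lists and H3K4me3 rose at each step in the number of factors in the region, whereas those of CTCF and H3K4me1 did not. Cohesin sites were at 18.2% of regions with 2 to 4 factors, 50.4% with 5 to 9, 78.2% with 10 to 19, 94.9% with 20 to 49 and 98.6% with 50 or more. MED12 was at 72.96% of regions with 10 to 19 factors and 99.5% with 50 or more, and MED1 at 21.4% and 98.5%. H3K4me3, a mark of promoters, was at 17.6% of regions with 10 to 19 factors and 95.2% with 50 or more. H3K4me1, found at enhancers and beside promoters, was at 49.9% of regions with 10 to 19 factors, 56.8% with 20 to 49 and 47.4% with 50 or more. CTCF was at 24.5% of regions with 5 to 9 factors (95% Wilson interval 23.8 to 25.2), 23.03% with 10 to 19 (22.3 to 23.8), 29.2% with 20 to 49 and 42.8% with 50 or more. Regions that touched an H3K4me1 peak and no H3K4me3 peak made up 44.2% of those with 10 to 19 factors, 34.1% with 20 to 49 and 2.43% with 50 or more.

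**Figure D2:**
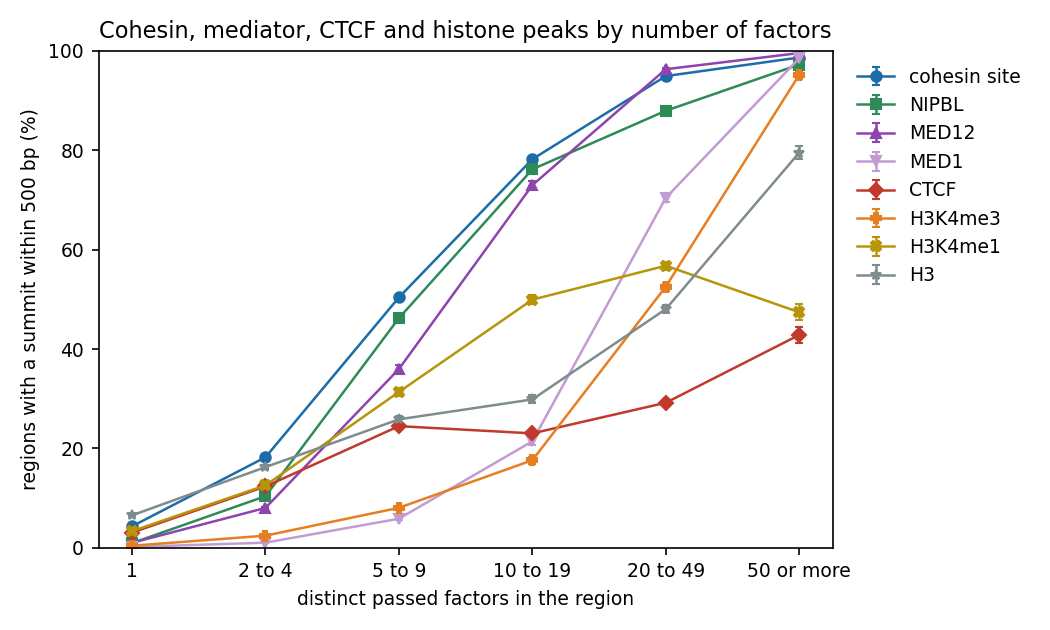
Percent of regions with a cohesin site or a summit of NIPBL, MED12, MED1, CTCF, H3K4me3, H3K4me1 or H3 within 500 bp, by the number of distinct passed factors in the region; bars are 95% Wilson intervals. Cohesin sites go from 4.32% of single-factor regions to 98.6% of regions with 50 or more factors, and CTCF from 3.07% to 42.8%.

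Of the dense regions, 60.8% had a cohesin site and no CTCF summit within 500 bp and 27.7% had both, and the values differed between regions built from the factors of 1 antibody host. Dense regions built from rabbit factors alone had cohesin without CTCF in 64.1% and both in 27.02% of cases, those from mouse factors 57.96% and 37.2%, and the 1020 from goat factors 36.6% and 59.4%. The cohesin, NIPBL and mediator libraries were made with rabbit antibodies and CTCF with a goat antibody, and 10 factors are a larger part of 19 goat than of 60 rabbit libraries, so these shares cannot be assigned to the host. In single-factor regions the share with both followed the same order, with 4.196% for rabbit, 6.07% for mouse and 8.07% for goat. The share with cohesin and no CTCF ran the other way there, with 2.25% for rabbit, 8.94% for mouse and 9.75% for goat. The CTCF library had 6967148 tags after filtering, and the cohesin libraries had 17904789 to 39747803. A site without CTCF therefore lacks a CTCF call and may still be bound, and the effect of depth was not tested. Seen from cohesin, 36070 of 64938 sites (55.5%) had no CTCF. These had a median of 10 factors within 500 bp, NIPBL at 58.7% and MED12 at 56.96% of sites, and H3K4me1 without H3K4me3 at 23.5%. The 28868 cohesin sites with CTCF had a median of 3 factors, NIPBL at 27.7%, MED12 at 32.5% and H3K4me1 without H3K4me3 at 3.26%. The 2209 CTCF summits without cohesin had a median of 1 factor.

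A given factor was at 13.1% ± 12.4 of cohesin sites without CTCF and at 7.47% ± 5.92 of those with it (SD over the passed factors). At CTCF summits without cohesin it was 4.47% ± 3.40. The paired difference was 5.59 ± 7.76 percentage points and positive for 95 factors and negative for 13 (two-sided sign-flip permutation test, p = 1e-05, the smallest possible). JUND (57.1% against 26.5%), MYC (54.6% against 24.6%), the circadian regulator CLOCK (36.4% against 8.55%), E2F2 (35.5% against 9.25%) and EVI1 (40.2% against 14.4%) had the largest differences in percentage points. Such differences can be larger for longer lists, and these lists held 20336 (E2F2) to 45040 (JUND) peaks. HNF4A, with 7109 peaks, was at 10.5% against 0.897%, so the ranking does not order factors by relative preference. The most negative differences were -8.89 for HINFP (10.8% against 19.7%), -7.52 for GLIS1 (3.06% against 10.6%), -2.33 for ATOH1, -2.06 for FEV and -0.993 for RBCK1. By antibody host the mean difference was 8.78 ± 8.40 for rabbit (positive for 57 factors and negative for 3) and 2.54 ± 4.599 for mouse (27 and 2; permutation p = 1e-05 for each). For goat it was 0.165 ± 3.81 (11 and 8; permutation p = 0.863), so the difference was not detected among goat factors. Single libraries moved this goat mean: it was -0.282 without E2F8, -0.109 without SOX2, -0.0888 without LHX2, 0.0962 without CAMTA2, 0.289 without FEV, 0.592 without GLIS1 and 0.668 without HINFP (lowest permutation p = 0.410). The mean difference was 3.88 in batch 1 and 8.61 in batch 2. It was 1.15 with the 2000 highest-scoring peaks of each list, 3.39 within 100 bp and 2.45 with cohesin sites called in any subunit, each with permutation p = 1e-05.

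**Figure D3:**
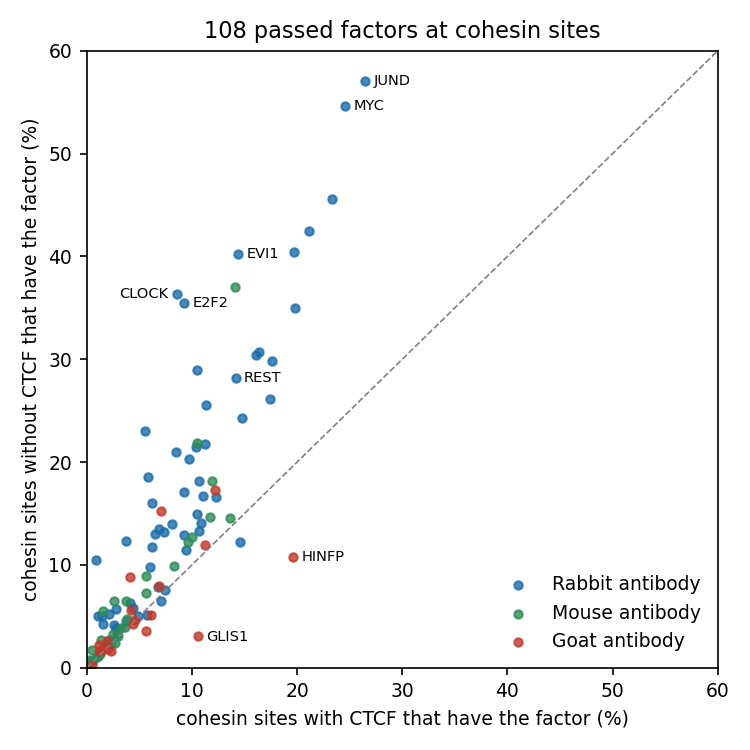
Percent of cohesin sites without CTCF (vertical axis) and with CTCF (horizontal axis) that had each of the passed factors within 500 bp; each point is 1 factor, coloured by antibody host, and the dashed line marks equal shares. In all, 95 factors lie above the line, with JUND and MYC farthest from it, and HINFP and GLIS1 lie farthest below it.

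Peaks of passed factors lay near cohesin more often than those of failed libraries. A cohesin site was within 500 bp of 57.02% ± 13.5 of the peaks of a passed factor (SD) and 23.3% ± 18.7 of those of a failed one (n = 99), a difference of 33.7 percentage points (two-sided permutation test, p = 1e-05, the smallest possible). CASP8AP2 (80.7%), GMEB2 (79.8%), SP1 (79.7%), GLI2 (78.8%) and NFAT5 (76.9%) had the highest shares among passed factors. TCF7L2 (21.7%), HINFP (24.1%), SMAD2 (29.4%), NR2F2 (31.3%) and NFIL3 (32.03%) had the lowest. The difference between passed and failed libraries was 30.5 in batch 1, 36.6 in batch 2, 20.1 for rabbit, 30.2 for mouse and 37.8 for goat antibodies, and 13.8 within 100 bp, each with permutation p = 1e-05.

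Factors with more crowded peaks had more peaks near cohesin. Both shares describe the same peaks, and 88.5% of dense regions had a cohesin site, so this relation in part restates that result. Across the passed factors both shares had a Pearson r of 0.925 and a Spearman rho of 0.918 (permutation p = 1e-05 for each, adjusted p of r = 1.8e-05 over 18 relations). The r was 0.914 without the 2 factors farthest from the median, 0.962 in batch 1 and 0.810 in batch 2. Crowded share and log10 peak number had an r of 0.169 (permutation p = 0.0793, adjusted p = 0.0892) and a rho of 0.257 (permutation p = 0.00713), with r of 0.221 without the 2 farthest factors. That r was 0.273 within batch 1 (0.205 without the 2 farthest factors) and -0.0108 within batch 2 (0.102 without the 2 farthest; adjusted p of r = 0.0281 and 0.949), and the difference between the batches was not tested.

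Factors differed widely in the marks at their peaks, and no family of related factors passed the test of either mark. For H3K4me1 outside H3K4me3 the mean share also differed by antibody host (19.03% for rabbit, 8.01% for mouse and 5.11% for goat). Both mark libraries were themselves made with rabbit antibodies. The family tests over all passed factors did not account for the host. The share of summits inside an H3K4me3 peak was highest for RFX1 (68.2%), the promoter-binding zinc finger YY1 (68.02%), SOX2 (61.8%), SP1 (55.5%) and FOXD2 (55.5%). It was lowest for TCF7L2 (3.37%), for HNF4A, a nuclear receptor of gut and liver epithelium (4.85%), and for HINFP (10.6%), ERM (15.8%) and GATA1 (16.98%). The share inside H3K4me1 and outside H3K4me3 was highest for ERM (41.4%), HNF4A (40.1%), HOXA2 (40.04%), CLOCK (38.7%) and ATF5 (36.96%). It was lowest for NR2F2 (0.267%), HINFP (0.520%), TFDP1 (0.586%), BARX2 (0.767%) and SMAD2 (0.839%), each made with a goat antibody.

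Of 11 families with at least 3 members and the 9 factors of no listed family, tested as a further group, 0 differed from the remaining factors in H3K4me3 share after Benjamini-Hochberg adjustment of two-sided permutation tests, and 1 did at an unadjusted p under 0.05. That family was the GATA type, with 22.3% ± 4.84 (n = 3) against 36.3% ± 11.7 in the remaining factors (exact permutation p = 0.0446, adjusted p = 0.494). RFX factors had 45.3% ± 19.9 (n = 3) and bZIP factors 30.8% ± 9.80 (n = 10). For H3K4me1 without H3K4me3, 0 families differed after adjustment and 0 at an unadjusted p under 0.05, and the lowest permutation p was 0.0728 for homeodomain factors, with 18.6% ± 11.6 (n = 12) against 12.99% ± 9.97 (n = 94; adjusted p = 0.765). With the 11 families alone the counts were also 0 after adjustment for each mark, and 1 (H3K4me3) and 0 (H3K4me1 without H3K4me3) unadjusted. Within batch 1 (11 groups) 0 differed for either mark after adjustment and 1 did for each mark at an unadjusted permutation p under 0.05, and within batch 2 (6 groups) 0 differed with or without adjustment.

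**Figure D4:**
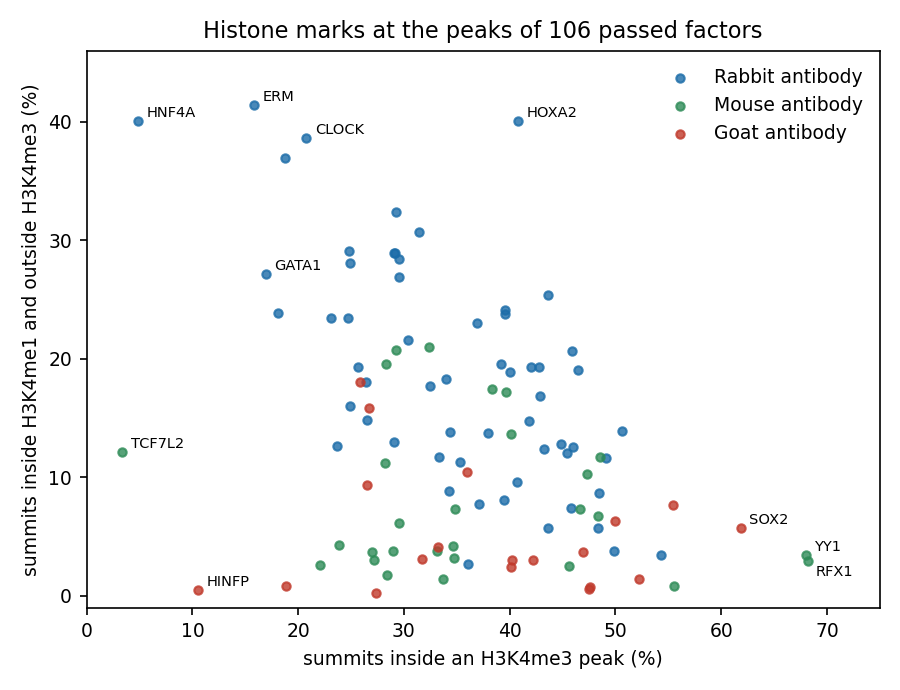
Percent of summits inside an H3K4me3 peak (horizontal axis) and inside an H3K4me1 peak but outside H3K4me3 (vertical axis) for the passed factors with at least 500 peaks (59 rabbit, 28 mouse and 19 goat antibodies), coloured by antibody host. HNF4A lies at 4.85% and 40.1%, and RFX1 and YY1 lie near 68% H3K4me3.

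Among 16 lists of partner factors, 1 stood out against the general crowding. For each pair of the passed factors with at least 500 peaks (59 with rabbit, 28 with mouse and 19 with goat antibodies), shared regions were compared with the number expected among regions with as many factors. The strongest list, of those fixed before the data were examined, joined NFYA, a subunit of the CCAAT-binding factor, with the GC-box factors SP1 and SP2. Its 3 pairs had a mean log2(observed/expected) of 1.25 against -0.02 ± 0.20 (mean ± SD) in random lists of 3. NFYA shared 988 regions with SP1 where 377 were expected (log2 1.39) and 1588 with SP2 where 632 were expected (log2 1.33), and SP1 shared 933 with SP2 where 460 were expected (log2 1.02). SMAD2 and SMAD3, signal transducers of the TGF-beta and activin pathway, shared 672 regions where 314 were expected (log2 1.09).

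Of the 16 lists, 1 passed a one-sided test against 10000 random lists, that of NFYA, SP1 and SP2 (p = 0.0002, Benjamini-Hochberg adjusted p = 0.0032). The SMAD list had an adjusted p of 0.0536 and passed, giving 2 lists in place of 1, under 7 of the 10 alternative settings, among them the one without HINFP. The histone gene regulators NPAT, CASP8AP2 and HINFP had a mean of 0.28, with each of their 3 pairs above 0 (adjusted p = 0.293). For the GC-box list of SP1, SP2, SP3, KLF3 and KLF5 it was 0.13 (adjusted p = 0.316), and for the GATA factors 0.13 (adjusted p = 0.362). The 8 colon enhancer factors had a mean of 0.06 (adjusted p = 0.362). In that list HNF4A and TCF7L2 shared 248 regions where 117 were expected (log2 1.08), and HNF4A and ASCL2 shared 822 where 1275 were expected (log2 -0.63). The lowest mean was that of HNF4A, RXRA, NR2F1 and NR2F2, which bind related sites (-0.49), and it rested on 1 pair. HNF4A (rabbit antibody) and NR2F2 (goat antibody, 750 peaks) shared 5 regions where 39.3 were expected (log2 -2.85). The mean of the other 5 pairs was -0.02, from -0.80 for HNF4A with NR2F1 to 0.62 for NR2F1 with NR2F2.

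The 7 remaining DNA-binding classes had pairs in both directions. The mean and SD over pairs was 0.07 ± 0.19 for HOX, 0.05 ± 0.24 for RFX, 0.03 ± 0.12 for CEBP and PAR factors, 0.02 ± 0.06 for the AP-1 site, -0.04 ± 0.09 for E2F and DP (5 of 6 members measured), -0.09 ± 0.42 for ETS and -0.09 ± 0.19 for E-box factors. ETS pairs went from -1.24 (ERM with FEV) to 0.62 (ETV7 with FEV), and E-box pairs from -0.53 (CLOCK with ARNT) to 0.15 (MYC with CLOCK). Single pairs gave 0.0042 for GMEB1 with GMEB2 and -0.03 for GLI2 with GLI3. The highest pair of all with at least 100 shared regions was RFX2 with ZBTB7B, with 2678 regions where 612 were expected (log2 2.13). KLF3 with NR2F2 (1.81), BARX2 with NFYA (1.81), NR2F2 with SMAD2 (1.79) and BARX2 with SP1 (1.66) followed. The next were IRX3 with NFIL3 (1.62), CAMTA2 with NR2F2 (1.59), NR2F2 with CREB3L4 (1.57), KLF3 with SMAD2 (1.47) and NR2F2 with GLIS1 (1.46).

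**Figure D5:**
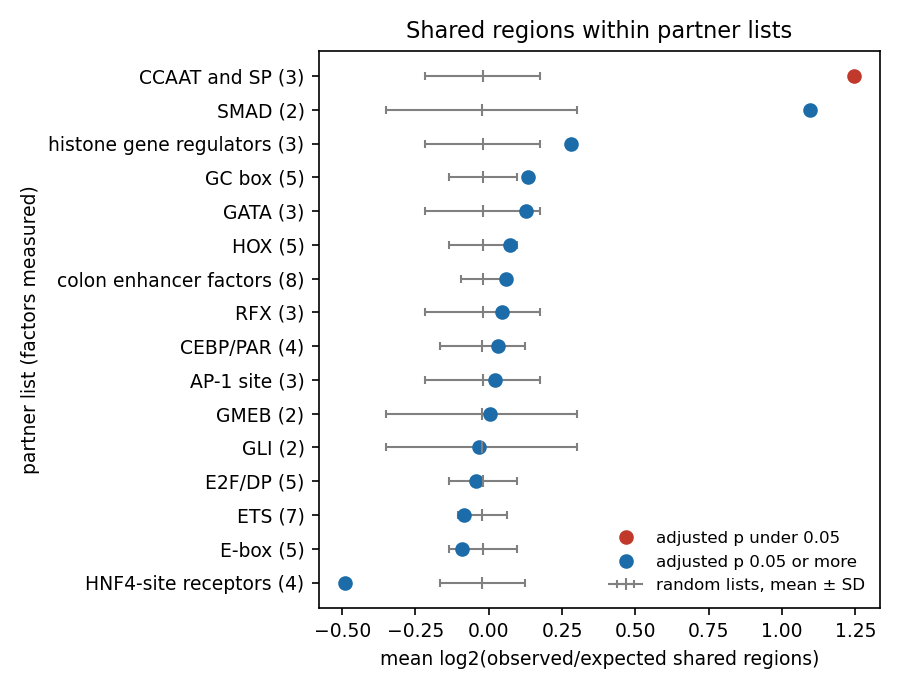
Mean log2 of observed over expected shared regions for the 16 partner lists (points), with the mean ± SD of 10000 random lists of the same size (grey). The number of factors used, those with at least 500 peaks, is in brackets. The list of NFYA, SP1 and SP2 has the highest mean, 1.25, and the HNF4-site receptors the lowest, -0.49 (-0.02 without the pair of HNF4A and NR2F2).

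No higher overlap was detected within families. The mean log2(observed/expected) was -0.031 for 386 pairs within families and -0.020 for 4270 pairs between them (difference -0.011, two-sided permutation of family labels over 97 factors, p = 0.564). Within batch 1 the difference was 0.012 and within batch 2 it was -0.046 (permutation p = 0.674 and 0.392). Broad classes gave much of the within-family set: 120 pairs were C2H2 zinc fingers outside the KLF and SP family (mean -0.01). Another 66 pairs each came from bHLH (0.01) and homeodomain factors (-0.05). Family means went from -0.14 for HMG-box factors (10 pairs) to 1.09 for SMAD (1 pair), so this result does not describe each family.

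On average, pairs that shared an antibody host overlapped more. Pairs with antibodies from the same species had a mean of 0.12 (2260 pairs) and other pairs -0.12 (3305 pairs), a difference of 0.23 (two-sided permutation of host labels over factors, p = 0.0001, the smallest that 10000 resamples can give). The mean was 0.63 ± 0.44 for 171 goat pairs, 0.28 ± 0.33 for 378 mouse pairs and 0.03 ± 0.17 for 1711 rabbit pairs (SD over pairs). Pairs of a goat with a mouse antibody had 0.06 ± 0.37 (532 pairs), which was above the rabbit pairs. Mouse with rabbit had -0.12 ± 0.24 (1652 pairs) and goat with rabbit -0.19 ± 0.37 (1121 pairs). Of the 10 highest pairs, 8 had antibodies from 1 species, against 40.6% of all pairs. The difference was 0.24 within batch 1 and 0.31 within batch 2, 0.46 with the 2000 highest-scoring peaks of each list and 0.39 without regions that touched H3K4me3 (permutation p = 0.0001 for each). Libraries of the same host also shared an IgG control, so host and control are the same variable here. NFYA, SP1 and SP2 were each made with a mouse antibody.

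Stronger peaks tended to be more crowded. Across the peaks of a factor, which are not independent replicates, the Spearman correlation between the authors' fold enrichment and the number of other factors within 500 bp had a mean of 0.194 ± 0.166 (SD over the passed factors with at least 500 peaks). It was positive for 96 of these factors (two-sided sign-flip permutation test, p = 1e-05, the smallest possible). MNT (0.644), RFX1 (0.640), ETS2 (0.615), NFYA (0.574) and MYC (0.562) had the highest values, and REST, the repressor of neuronal genes, had the lowest (-0.100), followed by GATA1 (-0.0952), JUN (-0.0385), HOXA7 (-0.0265) and HBP1 (-0.0200). The mean was 0.170 in batch 1 and 0.241 in batch 2. It was smaller among strong peaks, at 0.0416 in the better-scoring part of each list (the peaks above its median score; permutation p = 0.0137) and 0.0301 in its 2000 highest-scoring peaks (permutation p = 0.0932). It was 0.454 with the score in place of the fold and 0.0781 without the peaks that touched H3K4me3 (permutation p = 1e-05 for each).

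Libraries for which the labels name an enriched motif had a crowded share of 66.3% ± 14.7 (n = 33), against 59.4% ± 14.2 (n = 75) for the rest of the passed factors. The difference of 6.93 percentage points passed a two-sided permutation test (p = 0.0230) but missed the threshold under 8 of 12 alternatives. It was 9.09 in batch 1 (24 and 45 libraries, permutation p = 0.0234) and 2.72 in batch 2 (9 and 30 libraries, permutation p = 0.563).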

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

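The tests of differences between hosts or batches, and the comparison with shifted H3 lists, were chosen only after the results they bear on had been seen. The share of peaks near cohesin differed between passed and failed libraries by 20.1 percentage points among rabbit and 37.8 among goat antibodies, a difference between the hosts of -17.7 (permutation p = 0.00368, adjusted p = 0.0147 over 16 tests of batches and hosts). The difference between cohesin sites without and with CTCF was 8.78 percentage points for rabbit factors, 8.61 above that of goat factors (permutation p = 0.0001, adjusted p = 0.0016) and 6.24 above that of mouse factors (permutation p = 0.00036, adjusted p = 0.00288). It was 3.88 in batch 1 and 8.61 in batch 2, a difference of -4.73 (permutation p = 0.00165, adjusted p = 0.0088). Passed lists were longer in batch 2 (median 14335 peaks) than in batch 1 (7860). They were also longer for rabbit (mean log10 peak number 4.04) than for mouse (3.72) or goat (3.70). Longer lists can reach more sites, and these tests were not repeated with lists of equal length. Cohesin libraries share the rabbit host, and CTCF the goat host, with the factors compared here.

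The H3 library had a summit within 500 bp of 44.2% of dense regions, against 6.54% of single-factor regions. The length of dense regions is argued against, since the difference of 37.7 percentage points lay far above the shifted lists (mean 2.16, highest 2.73). Promoters are argued against as the whole source, because 28.2% of the 17107 dense regions without H3K4me3 had an H3 summit, though the share was 65.3% with H3K4me3. By position, 77.98% of the H3 summits near dense regions lay between the first and last factor summit. That share was 93.9% for MED12, 81.2% for H3K4me3 and 47.8% for H3K4me1. A signal that only follows open chromatin at the bound sites stays open, since no list measured open chromatin to set against these shares. The depth of this library and its rabbit IgG control were not tested, no biological explanation was tested, and histones flanking the bound sites remain a hypothesis.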

How the results depend on the processing

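The alternatives numbered 237, of which 195 were set in advance and 42, with the tag size, peak number covariate, region middle, marker list, sequence, family pair, host centring, HINFP, rabbit family, family set, cohesin by host and product settings, were chosen after seeing the data. In 207 the result stayed as reported, which for tests meant the same direction and the same side of the threshold. For counts it meant the same number or one within a fixed ratio of it. The number of dense regions moved by construction, since fewer peaks or libraries entered or the required number of factors moved: 17468 above the median score of each list, 5728 with the 2000 highest-scoring peaks, 45410 with 5 factors, 17788 with 20 factors, 13504 with 1 factor per family (27 libraries), 18069 in batch 1, 19310 in batch 2, 3899 for mouse, 1020 for goat and 16948 without H3K4me3. Each of these counts that was tested against shifts kept p = 0.0099. Cohesin at dense regions differed by 58.2 to 91.3 percentage points over 22 alternatives, mediator by 53.1 to 86.1 over 15 and NIPBL by 70.4 to 88.8 over 13; leaving out 1 cohesin subunit gave 72.5 to 77.5 and leaving out 1 mediator subunit 53.4 to 86.1. The number of partner lists past the threshold was 2 in place of 1, with SMAD as the other list, under a region gap of 1000 bp, a smallest list of 2000 peaks, regions without H3K4me3, no bins, host centring, HINFP left out and the product method; the cause was not tested. The difference between cohesin sites without and with CTCF fell to 0.165 (p = 0.863) with goat factors alone, a subset of 19 libraries; it passed for mouse (2.54) and rabbit (8.78). The family difference in pair overlap, which passed no test, turned positive with the 2000 highest-scoring peaks (0.012, p = 0.743), a smallest list of 2000 peaks (0.00053, p = 0.976) and batch 1 alone (0.012, p = 0.674). Peak strength and crowding had a mean rho of 0.0301 (sign-flip permutation p = 0.0932) with the 2000 highest-scoring peaks, and the cause was not tested. The motif label difference no longer passed above the median score of each list (6.24, p = 0.0716), with the 2000 highest-scoring peaks (6.04, p = 0.118), within 100 bp (4.81, p = 0.0507), with 20 factors (3.79, p = 0.184), in batch 2 (2.72, p = 0.563), and for rabbit (3.16, p = 0.310), mouse (9.06, p = 0.219) and goat antibodies (13.4, p = 0.162), all by permutation; the subsets hold fewer libraries, and for the rest the cause was not tested. List length rose with depth (Pearson r of 0.522 in passed and 0.748 in failed libraries), but depth was not tested as the cause of short lists: 21 failed and 2 passed lists held under 500 peaks, among them RARA with 176 peaks from 15567883 tags and OTX1 with 373 from 10216480. No paired analysis was possible because replicate numbers only follow accession order; this holds for samples of different groups, while the comparison of cohesin sites paired each factor with itself.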

Other observations

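In this part, the comparison of marks between hosts, the interval on HINFP folds and the setting without pairs of the same family were chosen only after the results they bear on had been seen. Some libraries that had failed were as crowded as passed ones. Of the 78 failed libraries with at least 500 peaks, 3 lay above the passed median of 62.9%: ISL1 (84.2%, list of 1602 peaks), NKX2-5 (74.3%, 7976) and HOXB13, a homeodomain factor of the hindgut and prostate (73.8%, 19417). FOXO3 (62.6%, 3250 peaks) and the histone acetyltransferase EP300 (59.4%, 8907) followed. Of these, FOXO3 was made with a mouse antibody and the others with rabbit antibodies. Failed rabbit libraries with at least 500 peaks had a mean crowded share of 44.1%, against 19.5% for mouse and 18.4% for goat. Factors of intestinal identity and Wnt signalling among the failed libraries, each with a rabbit antibody, gave 40.3% for CDX2 (1545 peaks), 35.8% for LEF1 (4387) and 33.7% for SOX9 (3707). At the other end, 6 failed libraries with at least 500 peaks were under 5% crowded. ISL1 peaks were near cohesin in 81.3% of cases, above the 80.7% of CASP8AP2, the highest passed factor.

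Rabbit libraries had more summits in H3K4me1 outside H3K4me3 than goat or mouse libraries. This share was 19.03% ± 9.74 for 59 passed rabbit libraries, 8.01% ± 6.36 for 28 mouse and 5.11% ± 5.14 for 19 goat libraries (SD). Rabbit was higher than goat by 13.9 and than mouse by 11.02 percentage points (permutation p = 1e-05 for each, the smallest possible, adjusted p = 6.75e-05 over 54 tests). Mouse and goat differed by 2.90 (adjusted p = 0.194), with an adjusted p of 0.597 in batch 1 and 0.0072 in batch 2. Within batch 1 the means were 14.3%, 5.23% and 3.84%, and within batch 2 they were 27.6%, 16.4% and 6.53%, for rabbit, mouse and goat. Failed libraries had the same order, with 26.95% ± 12.9 (n = 21), 12.4% ± 8.66 (n = 28) and 4.67% ± 6.69 (n = 29). The share inside H3K4me3 of passed libraries was 34.97% for rabbit, 36.7% for mouse and 37.9% for goat (adjusted p from 0.471 to 0.808). Within batch 2, however, it was lower for rabbit (32.4% ± 10.04, n = 21) than for goat (43.96% ± 11.8, n = 9; permutation test, adjusted p = 0.024), and in batch 1 the means were 36.4% for rabbit and 32.5% for goat (adjusted p = 0.478). Among failed libraries it was higher for rabbit than for mouse (14.99% against 9.97%, adjusted p = 0.0276), with 10.8% for goat. The H3K4me1 and H3K4me3 libraries share the rabbit host and its IgG control with the rabbit factors. Passed rabbit lists were also longer (mean log10 peak number 4.04, against 3.72 for mouse and 3.70 for goat). Differences in marks between hosts therefore cannot be assigned to the factors.

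On average, pairs with the same antibody host overlapped more than others. Calls near the threshold are argued against by the peaks above the median score of each list, where the difference was 0.26, and related factors raised in the same host by a difference of 0.23 without pairs of the same family. Batches are argued against by the lower of the differences within batch 1 and batch 2, 0.24. Independent shifted lists gave 0.037 at most. Such lists have almost no dense regions, so they do not show how large the method's offset is among crowded lists. What stays open is a background shared through the host or its IgG control: passed libraries overlapped more with the failed libraries of their own host than with those of other hosts, by 0.59 on the log2 scale over 78 failed libraries (permutation p = 0.0001, the smallest possible). Such a background may therefore account for part of the high goat pairs, NR2F2 with KLF3 among them, and no biological explanation was tested.

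HINFP had the lowest crowded share, and 20337 of its 39623 peaks on chromosomes 1 to 22 and X (51.3%) had no other passed factor within 500 bp. These lone peaks were in H3K4me3 in 0.162% of cases and near an H3 summit in 19.2%. Of the lone peaks, 5.47% lay near a peak of any of the 45 failed goat libraries, so few of them recurred in those lists. A background of goat antibodies stays open, because lone peaks by definition lie apart from the other passed factors, goat ones included. Peaks shared with those factors were left out of the test. The 5.47% was above shifted lists (mean 3.39%, highest 3.82%), whereas the shares near failed rabbit and mouse peaks, 2.21% and 2.93%, were below theirs (means 3.77% and 4.01%). Weak calls stay open: the median fold of lone peaks was 2.96, against 2.94 for crowded peaks, with a bootstrap interval of the difference from -0.01 to 0.06. HINFP binding apart from other factors, or a second target of this antibody, may explain the list, and neither was tested.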
